A study of Mus musculus with 8 samples.

How the data were processed

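RNA sequencing measured gene expression in mouse CD4 T cells of 2 genotypes, wild type and Ikzf4 knockout. Ikzf4 encodes Eos, a zinc-finger transcription factor of the Ikaros family. Per the labels' protocols, naive cells were stimulated through CD3 and CD28 on coated plates under conditions that favour Th1 cells, and total RNA was taken after 72 h. Each genotype had 4 libraries, numbered 1 to 4 in their titles, and the labels give C57BL/6J as the strain of both genotypes. The labels do not say whether the numbers stand for separate animals, litters or culture days, so the p-values measure the spread between these libraries, which may be partly technical.

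The authors deposited 1 table with whole-number read counts per gene for the 8 libraries, 49040 genes named by symbol, beside their own comparison of the genotypes. Per the submitters' processing notes, the tools included STAR 2.5.2, featureCounts of Subread 1.5.2 and DESeq2, with the genome build GRCm38. Alignment settings, the annotation, the strand setting of the counting and the treatment of reads with several matches are not given in the sources used here. Genes that overlap or share sequence with a near-identical copy are therefore uncertain. Per the file headers, the table also holds the authors' log2 fold changes, p-values and adjusted p-values from DESeq2, together with a mean normalized count (a signal scaled by library), a standard error on the log2 scale and a test statistic (a score). The sign of the authors' log2 fold change is wild type over knockout, which is opposite to the sign used in the text. DESeq2 run on the deposited counts gave log2 fold changes that differed from the authors' by at most 0.000186 after the sign was turned, and both made 225 calls.

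Library totals ran from 25227017 to 53149322 counts. Of the 49040 genes, 27828 had a count in at least 1 library, and 14672 were tested after edgeR's filter on low counts; these held 99.9% of all counts. No 2 libraries of a group were alike within sampling noise: the chi-square per degree of freedom between libraries of a group was 14.5 or more. The test was edgeR 4.0.16 (quasi-likelihood, TMM factors, genotype as the only term) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use the same TMM factors, log2 CPM values a prior count of 2, and errors of group means are SDs of 4 libraries. The smallest 2-sided p that an exact permutation test of 4 against 4 libraries can give is 0.0286.

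The analysis fixed beforehand had genotype as its only term, and the replicate number as a block was one of its alternatives, because the labels do not say that the numbers pair the libraries. The decision to describe most genes and lists from the blocked fit was made after the pairing and both sets of calls had been seen. The numbers paired the libraries. Same-numbered libraries deviated together from their group means, with correlations across genes from 0.61 to 0.73. Each of the 8 libraries correlated best with its own number, and of the 24 ways to match the numbers the deposited one gave the highest mean, 0.673 against 0.579 for the next. The source of the pairing is these values, since the labels name no shared litter, day or batch. Blocked values are given wherever the block changed a call.

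Each fit was tested on its own simulated data: counts for the same 14672 genes with the means and spread that this fit estimated, and 200 genes changed by known folds. A list of 20 further genes was raised 1.5-fold. Calls among these 20 count as true but are left out of the recoveries. The data for the blocked fit held the pairing of these libraries, and those for the fit without the block held none. The recoveries of the 2 fits are therefore not from the same data. For this comparison, the fit without the block recovered 3 of 67 genes changed 1.5-fold, 21 of 67 changed 2-fold and 51 of 66 changed 4-fold, with 5 false calls among 83. The blocked fit recovered 38 of 67, 51 of 67 and 65 of 66, with 15 false calls among 179.

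The design, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The lists, 30 in all, covered T helper programmes, cytotoxicity, IL-2 signalling, interferon responses, metabolism, stress, other cell types and library quality. Lists with at least 3 measured members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry. Named genes are the Ikaros family, the 10 largest called changes in each direction with no overlap between groups at 1 CPM or more (unnamed gene models and pseudogenes left out), up to 3 called members of each list per direction, 17 fixed T cell genes and the 5 smallest p-values per direction. Applied to the fit without the block, or as fixed genes, the rule took 40 genes; its use on the blocked fit was added after the data were seen and raised this to 99, of which the text names those that carry each comparison. Positions came from the GENCODE annotation of GRCm38 by symbol, for 14515 of the 14672 genes tested.

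Alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, no filter and a stricter filter (5 CPM in 4 libraries), limma-voom, the replicate block, each library left out in turn, and windows of 2 and 10 Mb around Ikzf4. Chosen after the data were first seen were a term for the sex of the animals, a term for library size (its bounds were written before its own result was seen), the fits without the libraries numbered 2, DESeq2 with the block, and every alternative to the blocked fit. All per-sample columns of the table were used. Sequence reads were not used here.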

Results

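Gene expression was measured by RNA sequencing in 8 libraries of mouse CD4 T cells, 4 from wild-type and 4 from Ikzf4 knockout cells, after 72 h of stimulation under Th1-polarising conditions. Wild-type libraries held 43958781, 35423558, 31101529 and 25893792 counts, and knockout libraries 35188755, 53149322, 25227017 and 26314178. The 10 most abundant genes took 4.51% to 5.82% of the counts in each library. The comparison sets cells with a knockout of Ikzf4, which encodes the Ikaros-family factor Eos, against wild-type cells. A difference in background between the mice, taken up at the end, cannot be told apart from the loss of Eos for the changes below.

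Ikzf4 itself was lower in every knockout library. Its level was 46.4 ± 6.55 CPM in wild type and 3.31 ± 1.22 CPM in the knockout (mean ± SD, n = 4 each), so 7.13% of the wild-type level remained. Counts per library ran from 1386 to 1814 in wild type and from 75 to 139 in the knockout. The change was -3.82 ± 0.27 on the log2 scale (SE; 14.1-fold; edgeR without the block, adjusted p = 0.000505), and the groups did not overlap (2-sided exact permutation test, p = 0.0286, the smallest that 4 against 4 libraries can give). Ikzf4 lies on chromosome 10 from 128630843 to 128645991 (GRCm38, minus strand).

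Of the other Ikaros-family genes, Ikzf2, which encodes Helios, and Ikzf3, which encodes Aiolos, were lower in the knockout in the blocked fit. Ikzf2 fell by 1.38 ± 0.13 on the log2 scale (edgeR adjusted p = 0.00085), from 14.4 ± 5.84 to 5.71 ± 3.12 CPM. Ikzf3 fell by 0.84 ± 0.08 (adjusted p = 0.00087), from 61.7 ± 13.2 to 35.0 ± 10.3 CPM. Both were lower in the knockout in all 4 same-numbered pairs. Ikzf1, the founding member, stood at 443 ± 37.8 and 479 ± 42.0 CPM, and Ikzf5 at 6.88 ± 2.41 and 7.01 ± 0.80 CPM; neither was called. Without the block, Ikzf4 was the only member called over all genes (3 fell adjusted over the list alone), with adjusted p = 0.431 for Ikzf2 and 0.348 for Ikzf3. The list test (camera, blocked, adjusted p = 1.27e-14) includes the deleted gene itself, so it says little about the other 4 members.

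**Figure D1:**
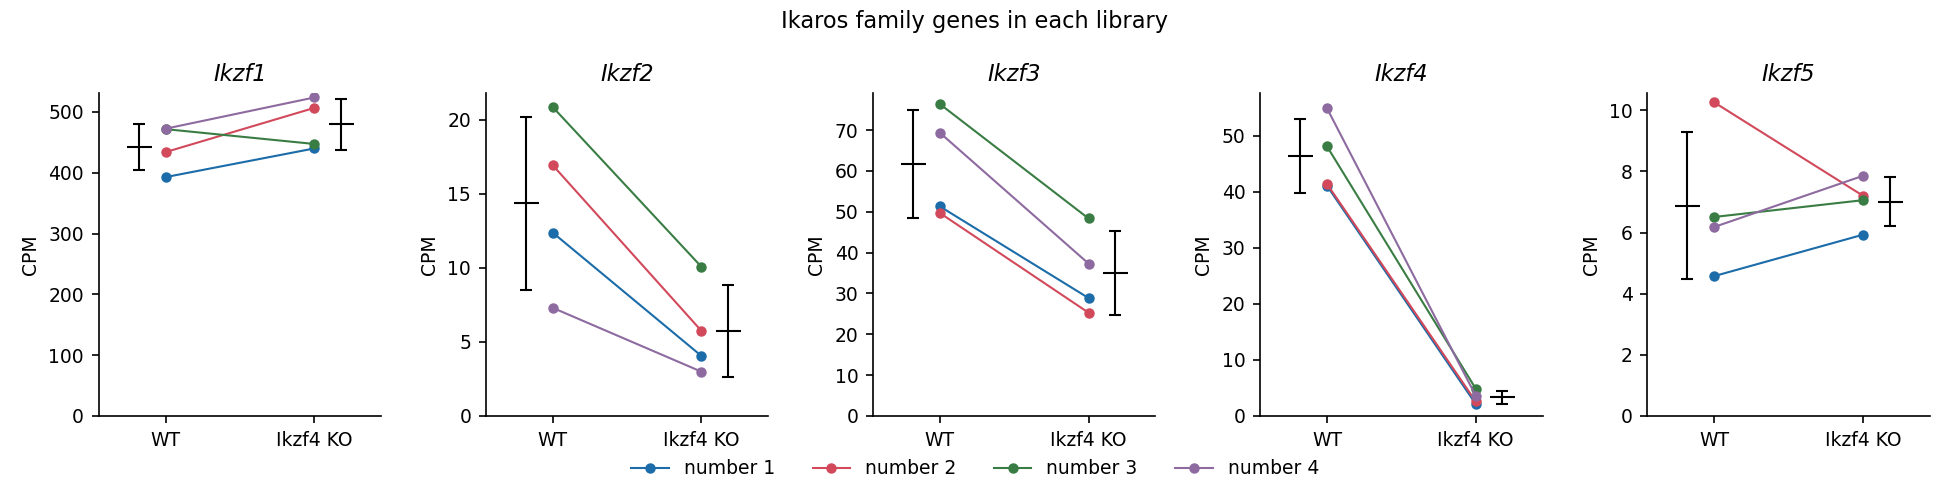
CPM of the 5 Ikaros-family genes in each library, on linear axes that start at 0; lines join libraries with the same number, and bars are the mean and SD of 4 libraries. Ikzf4 dropped from 46.4 to 3.31 CPM, and Ikzf2 and Ikzf3 were lower in the knockout in all 4 pairs.

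The analysis fixed beforehand, without a block, called 23 of 14672 genes (edgeR quasi-likelihood), 8 higher and 15 lower in the knockout, with 1189 genes at an unadjusted p under 0.05. With the replicate number as a block 984 were called, 395 higher and 589 lower, among them all 23, and 372 of the 984 changed by 2-fold or more. Values below are from the blocked fit unless stated, a choice made after both results were seen, and most of its calls are absent without the block. Of the 984, 973 changed the same way in all 4 pairs. The blocked test favours genes whose pairs agree, so this count follows largely from the calls and adds no support to them. The authors' deposited table, made without a block, called 225 genes, of which 218 were tested here and 216 were also called in the blocked fit. In 362 genes every knockout library lay above every wild-type library, and in 366 every knockout library lay below; together these are 4.96% of the genes tested, where chance gives 2.86% if all 8 libraries are exchangeable, which libraries paired by number are not.

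Many cytotoxic genes fell. Of 19 measured members, 12 fell, 1 rose and 6 were not called in the blocked fit (13 down and 1 up adjusted over the list alone), with a median change of -1.42 on the log2 scale. Gzmb, the protease of cytotoxic granules, dropped from 2513 ± 1355 to 525 ± 327 CPM, a change of -2.25 ± 0.15 (4.76-fold; adjusted p = 0.000201). Prf1, the pore-forming perforin, dropped from 113 ± 86.4 to 23.8 ± 20.4 CPM (-2.22 ± 0.16, adjusted p = 0.000232). Gzmd and Gzme, 2 further granzymes, changed by -3.43 ± 0.25 and -2.91 ± 0.31 at levels under 3 CPM in wild type, and the receptor gene Klrd1 by -2.26 ± 0.21. Crtam, a surface molecule of activated T and NK cells, went the other way, with +0.996 ± 0.21 (adjusted p = 0.0284), a call lost when the pair numbered 2, 3 or 4 was left out. At the preset correlation camera also passed up to 15 lists for other splits of these libraries, so its small p-values overstate the evidence. The list was lower in the knockout by camera with the block (adjusted p = 5.35e-29) and with an estimated correlation (adjusted p = 0.0453). The latter was lost whichever pair was left out (camera adjusted p = 0.125 to 0.21). The Ikaros, Th1 and regulatory lists had the same camera adjusted p of 0.0453. This tie of the Benjamini-Hochberg adjustment is set by the largest p of the 4 lists, and the Ikaros list among them holds the deleted gene. None of the other lists is thus shown to pass by itself. Without the block edgeR called no member over all genes and 8 fell adjusted over the list alone. The list kept its direction (camera adjusted p = 2.33e-12, and 0.0336 with an estimated correlation, a value tied with that of the Ikaros list). DESeq2 without the block called Gzmb (adjusted p = 0.000158) and Gzmd (1.81e-06), for example, but not Prf1 (0.201).

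Among the Th1 genes, Ifng fell while Tbx21 was not called. Of 24 measured members, 12 fell, 0 rose and 12 were not called (15 down and 1 up adjusted over the list alone). Ifng, the signature Th1 cytokine, dropped from 1332 ± 375 to 600 ± 211 CPM (-1.17 ± 0.08, 2.25-fold; adjusted p = 0.000232). The chemokine receptor gene Cxcr6 changed by -2.07 ± 0.15, and the chemokine gene Ccl4 by -1.30 ± 0.12. Tbx21, which encodes the Th1 master regulator T-bet, stood at 221 ± 52.5 CPM in wild type and 217 ± 43.3 CPM in the knockout (-0.02 ± 0.07, adjusted p = 0.886), and Cxcr3 changed by -0.06 ± 0.21. The list was lower by camera with the block (adjusted p = 4.15e-15, and 0.0453 with an estimated correlation, which became 0.129 to 0.21 when any pair was left out). Without the block edgeR called 0 members over all genes and 2 fell adjusted over the list alone (camera adjusted p = 4.44e-05, and 0.17 with an estimated correlation). DESeq2 without the block called Ifng (adjusted p = 0.00679) and Cxcr6 (3.13e-08), but not Ccl4 (0.131).

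**Figure D2:**
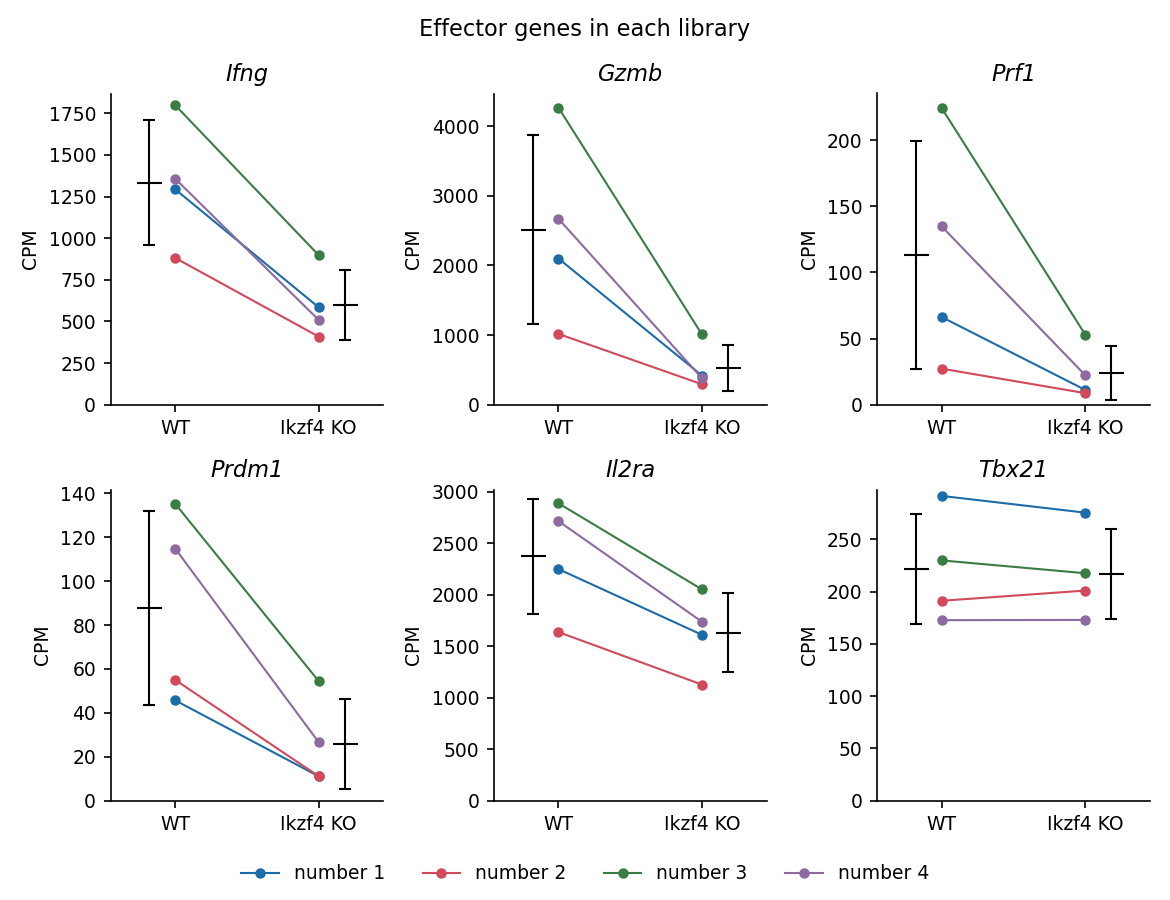
CPM of Ifng, Gzmb, Prf1, Prdm1, Il2ra and Tbx21 in each library, on linear axes that start at 0; lines join libraries with the same number, and bars are the mean and SD of 4 libraries. The first 5 genes were lower in the knockout in all 4 pairs, whereas Tbx21 had means of 221 and 217 CPM.

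Some genes of the IL-2 and STAT5 pathway fell. Of 21 measured members, 9 fell, 0 rose and 12 were not called (10 down and 1 up adjusted over the list alone). Prdm1, which encodes the repressor Blimp-1, changed by -1.93 ± 0.15 (adjusted p = 0.000362), from 87.7 ± 44.1 to 25.8 ± 20.4 CPM. The receptor chains Il2ra and Il2rb changed by -0.54 ± 0.06 (adjusted p = 0.00184) and -0.65 ± 0.08 (adjusted p = 0.00187), and the survival gene Bcl2 by -0.49 ± 0.07. Stat5a (+0.24 ± 0.10), Stat5b (-0.01 ± 0.09) and Il2 (+0.31 ± 0.19) were not called. The list was lower by camera with the block (adjusted p = 3e-08), but not with an estimated correlation (adjusted p = 0.168 with the block and 0.104 without it). Without the block edgeR called no member over all genes and 1 fell adjusted over the list alone.

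Some regulatory T cell and co-inhibitory genes fell, others rose or were not called. Of 18 measured regulatory genes, 8 fell, 1 rose and 9 were not called (9 down and 2 up adjusted over the list alone); Il2ra and Ikzf2 also stand in other lists. The cytokine gene Il10 changed by -2.48 ± 0.18 (adjusted p = 0.000251), the ectonucleotidase gene Entpd1 by -2.30 ± 0.16, and the inhibitory receptor gene Ctla4 by -1.09 ± 0.12. Nrp1, which encodes neuropilin-1, rose from 16.7 ± 2.42 to 43.6 ± 8.99 CPM (+1.37 ± 0.09 with the block and +1.38 ± 0.17 without it, adjusted p = 0.000232 and 0.0187). Foxp3, the defining factor of regulatory T cells, was low in both groups, with 6.98 ± 4.50 and 4.10 ± 4.07 CPM, and was not called (adjusted p = 0.0992). In the list of activation and co-inhibitory receptors, 6 of 22 fell, 3 rose and 13 were not called (8 down and 8 up adjusted over the list alone). Havcr2, which encodes TIM-3, changed by -1.87 ± 0.12 and Tigit by -0.77 ± 0.10, while Tox, a factor of chronically stimulated and follicular T cells, changed by +1.44 ± 0.21. The regulatory list was lower by camera with the block (adjusted p = 2.27e-10, and 0.0453 with an estimated correlation, which became 0.125 to 0.239 when any pair was left out). Without the block Nrp1 was the only member that edgeR called over all genes (camera adjusted p = 0.00831, and 0.416 with an estimated correlation). The activation list had no direction of its own (adjusted p = 0.273).

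Some follicular helper and type I interferon genes rose. In the follicular list 5 of 17 rose, 0 fell and 12 were not called (8 up and 2 down adjusted over the list alone). The surface genes Cd200 and Btla changed by +0.64 ± 0.07 and +0.47 ± 0.06, and Tcf7, which encodes TCF-1, by +0.52 ± 0.08 (call lost without the pair numbered 3), whereas Bcl6, the defining factor of follicular helper cells, was not called (+0.38 ± 0.16, adjusted p = 0.215). In the interferon list 5 of 25 rose, 0 fell and 20 were not called (9 up and 0 down adjusted over the list alone). Ifih1, a sensor of double-stranded RNA, changed by +1.33 ± 0.15 (adjusted p = 0.00146), Mx1 by +0.84 ± 0.15 and Oasl2 by +1.06 ± 0.21; leaving out the pair numbered 1 ended the calls of Mx1 and Oasl2, and leaving out the pair numbered 3 that of Oasl2. Camera at the preset correlation gave adjusted p = 0.00127 and 2.98e-05 with the block and 0.00831 and 0.0608 without it. With an estimated correlation neither list passed camera's threshold (adjusted p = 0.351 for both with the block; 0.188 and 0.727 without it). Without the block edgeR called no member of either list, whereas DESeq2 called Tox of the follicular list (adjusted p = 0.0404).

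Among naive and central memory genes, 4 of 15 fell, 4 rose and 7 were not called (5 down and 4 up adjusted over the list alone). The receptor gene Il7r changed by -1.02 ± 0.08 (adjusted p = 0.000394), while the repressor gene Bach2 changed by +0.49 ± 0.07 and Klf3 by +0.81 ± 0.13. Bach2 lost its call without the pair numbered 3. As a list these genes had no direction (camera, blocked, adjusted p = 0.656). Ccr7 (+0.03 ± 0.11) was not called. Of 18 chemokine receptor and homing genes, 6 fell, 2 rose and 10 were not called (8 down and 2 up adjusted over the list alone); the integrin genes Itga4 and Itgb1 changed by +0.69 ± 0.12 and +0.44 ± 0.07, and the integrin gene Itgb7 by -0.78 ± 0.11. Itga4 lost its call without the pair numbered 1, and Itgb1 without the pair numbered 1 or 3. This list was lower by camera (blocked, adjusted p = 1.24e-05, and 0.153 with an estimated correlation). Th2 genes had 1 called member in each direction, among them the low Il13 (1.90 and 5.63 CPM, +1.14 ± 0.28, call lost without the pair numbered 1, 3 or 4), and Gata3 stood at 11.4 ± 9.46 and 10.7 ± 6.81 CPM. Of 10 Th17 genes 1 fell. Camera with the block gave adjusted p = 0.0686 for the Th2 list and 0.0173 for the Th17 list (0.351 and 0.252 with an estimated correlation). In the lists of the interferon-gamma response, cell cycle, glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis, and the unfolded protein and ATF4 response, at most 1 member was called in the blocked fit, and none of these lists passed with an estimated correlation (adjusted p = 0.351 or more with the block). At the preset correlation their adjusted p-values from camera, with the block, were 0.0504, 0.0421, 0.00234, 0.0504, 0.065 and 0.007 in this order. The p53 list had 2 members up and 2 down (adjusted p = 0.813).

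**Figure D3:**
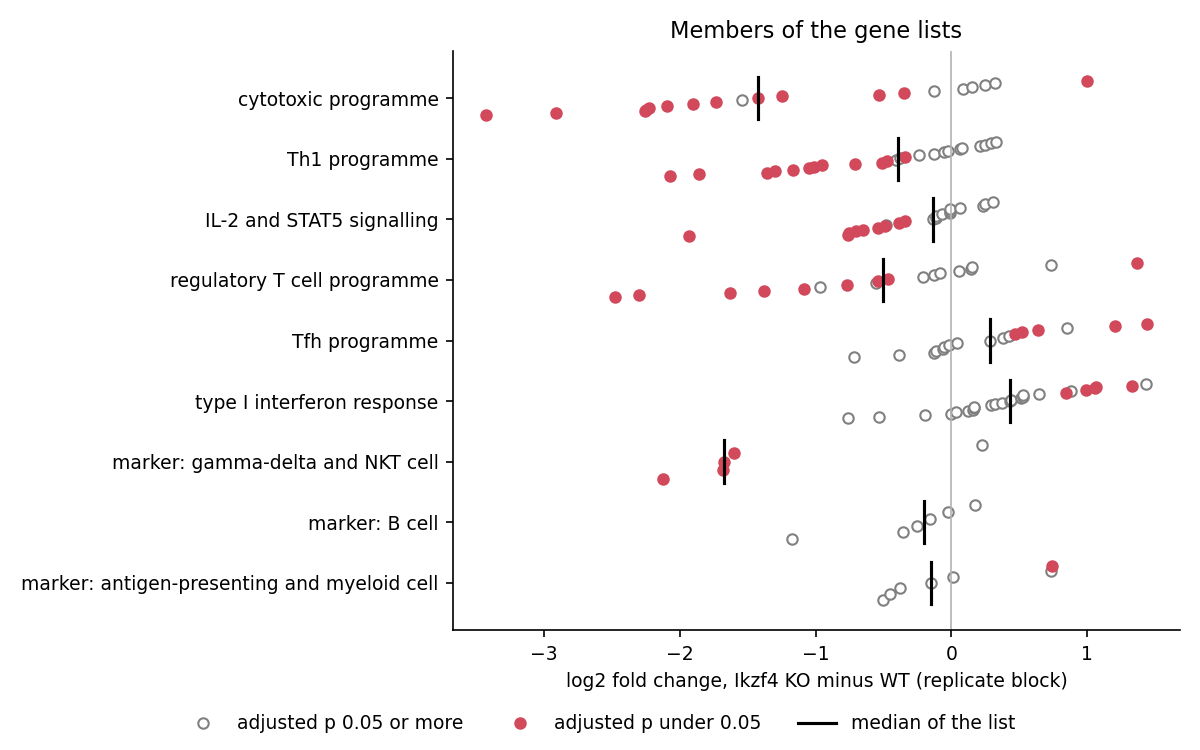
Log2 fold changes, knockout minus wild type, of the measured members of 9 gene lists in the blocked fit; filled points passed an adjusted p of 0.05, open points did not, and vertical bars are list medians. The cytotoxic list has a median of -1.42 and the list of gamma-delta and NKT cell genes one of -1.67.

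Markers of other cell types were examined beside these lists, because a culture can hold more than CD4 T cells. Genes of the gamma-delta T cell receptor were lower in the knockout together with the cytotoxic genes: 4 of 5 measured members of the gamma-delta and NKT list fell and none rose (also adjusted over the list alone), among them Trdc (-2.12 ± 0.18, from 12.6 ± 5.72 to 3.02 ± 1.91 CPM) and Tcrg-C2 (-1.68 ± 0.13). This list was lower by camera with the block (adjusted p = 6.14e-15), but not with an estimated correlation (adjusted p = 0.0876). NK cell genes were near the detection limit, with 3 measured and 1 called, Klre1 (1.29 and 0.505 CPM; call lost without the pair numbered 1, 3 or 4). Camera gave this list adjusted p = 0.0353 with the block and 0.351 with an estimated correlation. The CD8 genes Cd8a and Cd8b1 had 5.85 and 3.82 CPM in wild type and 3.37 and 4.36 CPM in the knockout. Of the B cell markers none was called among 6 measured, and of the antigen-presenting markers Cd74 alone rose among 7 (+0.74 ± 0.12); red cell, mast cell and granulocyte genes did not pass the filter on low counts. Below that filter, genes of mast cells and basophils had counts mainly in wild type 1 and wild type 3: Mcpt8 had 262 and 139 counts there, 0 in wild type 2 and 4, and 9 over the knockout libraries, and Cpa3 and Prss34 followed the same libraries. Camera gave the B cell and antigen-presenting lists adjusted p = 0.367 and 0.768 with the block. By Xist and Y-linked genes, the libraries numbered 2 came from female animals in both groups and the other 6 from males. Heat shock and immediate early genes had 0 called among 14 (camera, blocked, adjusted p = 0.217), while fry with the block placed the list higher in the knockout (adjusted p = 0.0273). Fry did not do so without the block (adjusted p = 0.733). With the block its call was lost without the pair numbered 2, 3 or 4 (fry adjusted p = 0.108, 0.14 and 0.138).

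Several of the strongest changes concerned genes with nearly complete loss or gain of counts; log2 changes of single genes in this paragraph are from the fit without the block. The mitochondrial gene mt-Nd3, a subunit of respiratory complex I, was at 0.221 ± 0.119 CPM in wild type and 14.7 ± 3.80 CPM in the knockout (+6.03 ± 0.38, edgeR adjusted p = 0.000505 without the block). Gm28438, an unprocessed pseudogene on chromosome 1 from 24612775 to 24613119 with 99.7% identity to the mt-Nd3 transcript, went the other way, from 22.3 ± 4.98 to 0.465 ± 0.218 CPM (-5.63 ± 0.36), so that both values are uncertain. The mitochondrial tRNA genes next to mt-Nd3 on either side, mt-Tg and mt-Tr, had 1 count each over the 4 wild-type libraries and 352 and 190 counts over the knockout libraries, ratios of 343 (95% interval 61.2 to 13593, counting error only) and 185 (32.8 to 7355). Both ratios are as uncertain as the values of mt-Nd3, because the treatment of reads with several matches is not given. Whether the tRNA genes share sequence with a copy beside Gm28438 was not examined, so the ratios may not measure tRNA levels. Gm12666 on chromosome 4 had 2 and 656 counts (ratio 320 with a 95% interval of 88.2 to 2646). Rpl34, a ribosomal protein gene, fell by 1.12 ± 0.08 while its near-identical pseudogene Rpl34-ps1 changed by +3.98 ± 0.36. Their summed level fell by 0.88 ± 0.04 (SE of 4 pairs), from 598 to 326 CPM. The split between the copies is uncertain, and so is the sum, because the treatment of reads with several matches is not given. Mitochondrially encoded genes as a list had 3 of 13 members higher with the block, and 10 not called. Besides mt-Nd3 the higher members were mt-Co3 and mt-Nd4l, whose calls were lost without the pair numbered 3 or 4, and mt-Co3 also without the pair numbered 1. Both were near the detection limit, mt-Co3 at 1.48 CPM in wild type and 2.62 CPM in the knockout, and mt-Nd4l at 0.44 and 1.34 CPM. They are uncertain too, because the treatment of reads with several matches is not given. The median of the list was -0.01 although camera placed it higher (adjusted p = 0.00498, and 0.454 with an estimated correlation).

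Protein-coding genes called in both fits, with values from the fit without the block in this paragraph, included Dock2, an activator of the GTPase Rac in lymphocytes. Dock2 was at 72.4 ± 23.6 CPM in wild type and 340 ± 63.4 CPM in the knockout (+2.23 ± 0.24, edgeR adjusted p = 0.00782 without the block). It is taken up again at the end as a gene that can mark a background. Fam46c (-1.26 ± 0.13), the mitochondrial calcium uniporter subunit gene Mcub (-1.73 ± 0.16), the adaptor gene Sla2 (-1.56 ± 0.17), the integrin gene Itga5 (-1.68 ± 0.22), Igsf23 (-1.48 ± 0.18), Coro2a (-1.25 ± 0.18) and the GTPase exchange factor gene Rasgrp2 (-1.63 ± 0.24) were lower. Dynlt1 (-1.87 ± 0.12) shares sequence with close paralogs and is uncertain. Leaving out single libraries ended the calls of Coro2a, Igsf23, Itga5, Nrp1, Rasgrp2 and Suox in the fit without the block.

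**Figure D4:**
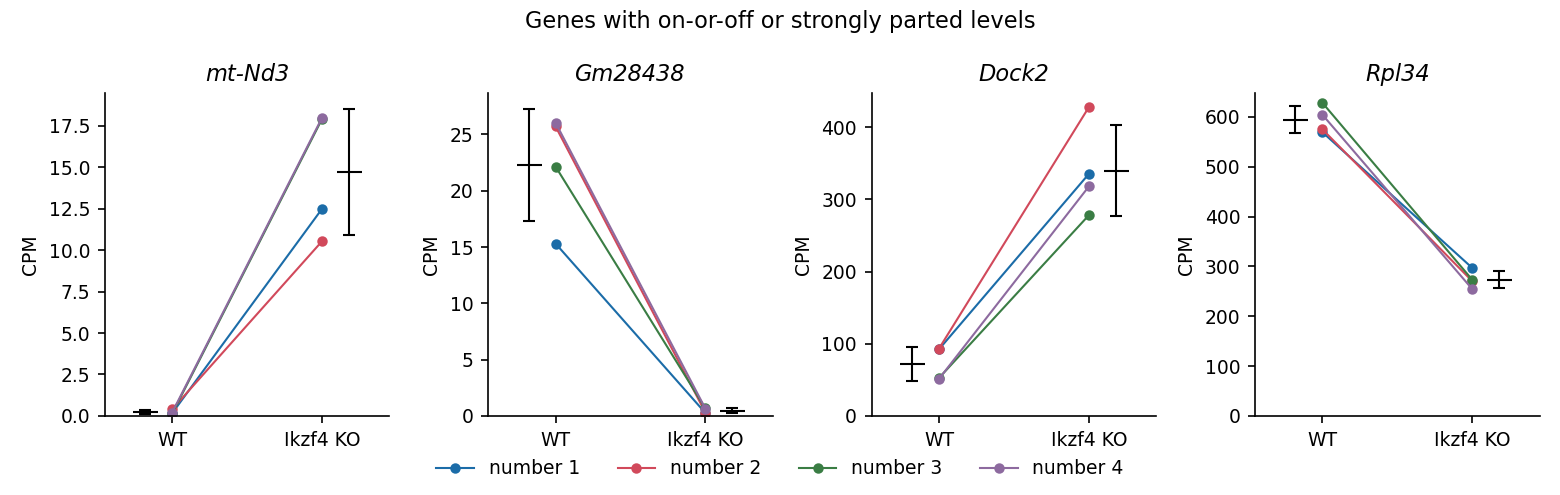
CPM of mt-Nd3, Gm28438, Dock2 and Rpl34 in each library, on linear axes that start at 0; lines join libraries with the same number, and bars are the mean and SD of 4 libraries. In each panel the 4 wild-type and 4 knockout libraries do not overlap.

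Genes next to Ikzf4 were examined because a targeted allele can alter neighbours. Suox, which encodes sulfite oxidase and lies 23.9 kb from Ikzf4 on chromosome 10 (128669894 to 128674073), dropped from 20.4 ± 1.63 to 3.46 ± 1.56 CPM (-2.56 ± 0.30 without the block, with adjusted p = 0.0143, and 0.000546 with it). Cd63, at a distance of 255 kb, was called with the block (-1.76 ± 0.29, adjusted p = 0.0104) but lost this call when the pair numbered 1 or 3 was left out. Of 29 measured genes of the neighbourhood list, these 2 were called with the block and 27 were not (camera, blocked, adjusted p = 0.0344, and 0.538 with an estimated correlation). Within 5 Mb of Ikzf4, 1 of 86 tested genes was among the 20 called genes with a position, Ikzf4 left out (odds ratio 8.92, Fisher's exact test, 2-sided p = 0.112). With blocked calls it was 4 of 86 among 972 (odds ratio 0.678, Fisher's exact test, p = 0.663).

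The first principal component of log2 CPM held 52.4% of the variance and separated the libraries numbered 1 and 2 from those numbered 3 and 4, and the next components held 16.1% and 14.2%. On the first component each knockout library also scored below the wild-type library of the same number. The second component parted the genotypes narrowly, with scores from 8.77 to 35.7 in wild type and from -43.8 to 8.29 in the knockout. Spearman correlations between libraries across genes ran from 0.954 to 0.993.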

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

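All 21 values below stood apart from the other 3 libraries of their group in a test for a single distant value, out of 220 groups of 4 values tested; about 1 in 20 such groups is expected to do so by chance. Of these, 14 came from the 198 groups of named genes.

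The sex-linked genes mark the libraries numbered 2. Xist was at 503 CPM in wild type 2 and 588 CPM in knockout 2, against at most 0.57 CPM elsewhere in the knockout group. Eif2s3y was at 0 CPM in both libraries numbered 2, where the other libraries held 88.1 CPM or more. Uty was at 0.028 CPM in wild type 2 and 0 in knockout 2, and Ddx3y at 0 in knockout 2.

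T cell regulators with 1 distant library were Gata3, with a log2 CPM of 4.68 in wild type 2 against at most 2.83 in the other 3, Foxo1, at 6.56 in wild type 1, and Stat5b, at 7.78 in knockout 2. The cytotoxic receptor gene Klrd1 was at 4.42 in wild type 3, above 3.44 in the next library. The integrin genes Itga4 and Itga5 were low in wild type 2, at 4.50 and 3.06. Fam46c was at 7.25 in wild type 4. Twist1 was high in wild type 1 at 3.08, and Pdzrn3 and Tenm4 were high in knockout 2 at 2.03 and 2.31. Gm7729 was at 0.46 in wild type 1. Only 2 counts set Gm12666 apart at -3.13 in wild type 2. A count of 1 did so for mt-Tg at -3.54 in wild type 2 and for mt-Tr at -3.46 in wild type 3, each among libraries with 0 counts.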

How the results depend on the processing

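The direction and the call of Ikzf4 held under every alternative run. Of the 20 named genes called without the block, 14 kept the call under every alternative set beforehand that tested them (the stricter filter did not test mt-Tg, mt-Tr and Gm12666), and 0 named genes changed sign while called. The 23 genes called became 225 with DESeq2 and 984 with the replicate block (paired libraries). Alternatives chosen after seeing the data gave 1385 with DESeq2 and the block, 40 with a term for sex, 41 with a term for library size, 11 without both libraries numbered 2, and 1437 without these and with the block. Leaving out 1 library gave 14 to 24, with 14 without wild type 3 or wild type 4 and 15 without knockout 4. The 984 blocked calls became 2124 with no filter and 640 with the stricter filter, which test 27828 and 9824 genes, and ran from 398 (without the pair numbered 3) to 1437 as each pair was left out, with 622 without pair 1 and 529 without pair 4. Of the 87 named genes called with the block, 63 kept the call whichever pair was left out. Camera's 14 lists became 2 with an estimated correlation, 2 with fry and 4 with the block and an estimated correlation (0 when any pair was left out), and 8 with the block and fry; leaving out 1 library gave 13 to 17. The 16 blocked lists ran from 12 to 18 as pairs were left out. The odds ratio for position turned from 8.92 to 0.678 with blocked calls, neither past the threshold. The cause was not tested. In data simulated without pairing, the fit without the block rarely recovered 1.5-fold changes at this depth and number of libraries. Called members of the lists went from 4 to 93 with the block, and to 2 without wild type 3 or wild type 4. With the block the Th17 (adjusted p = 0.0173), type I interferon (2.98e-05), glycolysis (0.00234) and NK cell (0.0353) lists passed camera's threshold, and the oxidative phosphorylation (0.0504) and cholesterol (0.065) lists no longer did.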

Other observations

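Beyond the fixed lists, the blocked fit held further genes of known function, chosen here after their values were seen. Lower in the knockout in all 4 pairs were Thy1, a T cell surface glycoprotein, with 530 and 240 CPM (-1.12 ± 0.08 on the log2 scale, edgeR adjusted p under the threshold as for all genes of this paragraph), the intermediate filament gene Vim (-0.87 ± 0.07), the interferon-gamma receptor gene Ifngr1 (-1.14 ± 0.11), the purine enzyme gene Xdh (-1.18 ± 0.07), the transcription factor gene Zbtb32 (-0.98 ± 0.08), the galectin genes Lgals1 (-0.73 ± 0.08) and Lgals3 (-1.46 ± 0.18), and Hopx (-1.07 ± 0.09), a gene of long-lived effector T cells. The stem-cell antigen genes Ly6a (-0.78 ± 0.09) and Ly6e (-0.86 ± 0.07) and the cysteine protease inhibitors Ctla2a (-1.54 ± 0.13) and Ctla2b (-1.88 ± 0.17) also fell; their families hold close copies, so single members are uncertain. Higher in all 4 pairs were the kinase gene Jak2 (+0.63 ± 0.07), the phosphatase gene Dusp6 (+0.98 ± 0.14), the growth factor receptor genes Igf1r (+0.88 ± 0.14) and Axl (+0.99 ± 0.14), Tmem173, which encodes the DNA-sensing adaptor STING (+0.55 ± 0.08), and Mpeg1, which encodes perforin-2 (+1.15 ± 0.12).

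The tests in the paragraphs that follow were chosen after the results were seen, except that the bounds for the splits of the libraries and for the term for library size were written before their results.

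Of the 35 splits of the 8 libraries into 4 and 4, 2 called at least the 23 genes of the genotypes without the block, the genotypes' own split among them, so chance cannot be excluded at that share; the other split called 3526 genes and parted no pair, which points to a structure of the libraries by number. Among the 8 splits that part all 4 pairs, the highest other count was 0 without the block. With the block the genotypes gave 984 and the highest other of the 8 was 0, 1 split reaching the real value; 8 splits are too few for a share under 0.05. For camera's lists without the block, 4 of the 35 splits, the genotypes' own among them, gave at least the 14 seen, the highest other giving 15, so chance cannot be excluded; among the 8 splits that part all pairs the highest other was 13, but 8 splits are too few for a share under 0.05. With the block the 16 lists compare with 15 in the highest other of the 8 splits, 1 split reaching the real value, again too few for a share under 0.05.

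The block raised the calls from 23 to 984. The sex of the animals is argued against, since a term for it gave 40 calls, and so is library size, whose term gave 41. A day, litter or culture shared by libraries with the same number may account for it: the mean correlation of same-numbered deviations was 0.673, the highest of 24 matchings. Which of these was shared stays open, because the labels name none.

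Genes with on-or-off levels outside chromosome 10 may mark a difference in background between the mice, although both genotypes are labelled C57BL/6J. Residual sequence of another strain on these chromosomes was not tested. The mt-Nd3 transcript and Gm28438 differ at 1 aligned base, T9461C, a site at which C57BL/6 substrains have been reported to vary. The name gives the mitochondrial base, its position counted from 1 on the GRCm38 mitochondrial genome, then the copy's base. Reads moving between the copies stay open, because their summed level changed by -0.58 ± 0.24 (SE of 4 pairs), between the bounds set. Of 6 other pseudogenes beside Gm28438, 2 were called lower with the block and the rest were not called. The 2 were Gm10222 (-2.24, edgeR adjusted p = 0.0128) and Gm28437 (-1.54, adjusted p = 0.00639). The mitochondrial genes mt-Co3, mt-Nd3 and mt-Nd4l, called higher with the block, lie between bases 8607 and 10173, around this site. A different substrain cannot be told apart from the genotype here: Nnt, disrupted in C57BL/6J, changed by -0.066 ± 0.12, but 1 shared locus excludes nothing. Dock2, Ide and Wdfy1 were examined with Nnt as genes that can mark a background. Ide (+0.96 ± 0.08), Wdfy1 (-1.47 ± 0.28) and Dock2 differed in all 4 pairs. Dock2 was the lower in wild type, with 72.4 CPM against 340 CPM in the knockout. A direct effect of Ikzf4 on these genes was not tested.

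Cytotoxic genes and gamma-delta receptor genes were lower together in the knockout. A lower share of CD4 T cells in the wild-type cultures, which would raise the markers of all other types alike, stays open. Markers under 10 CPM, summed per type, lay above the receptor genes by more than 2 SE in 2 of 3 types (antigen-presenting cells by 1.58 ± 0.09 and CD8 T cells by 1.28 ± 0.44 on the log2 scale, SE of 4 pairs), and by 2.01 ± 1.05 in B cells, whose counts rose in knockout 1. Mast cell and basophil genes, with counts mainly in wild type 1 and 3, go with this explanation in those libraries alone. Itgam (27 and 3 counts) and Tyrobp (33 and 6) were also lower in the knockout, but they are single markers with few counts. The 17 antigen-presenting markers that hold Itgam changed by -0.20 ± 0.20 when summed. Fewer gamma-delta or NK-type cells in the knockout cultures stay open. The changed cytotoxic genes, chosen because they changed, were 12 lower and 1 higher, Crtam, whose rise makes their mean fall smaller. Together they differed from the receptor genes by 0.14 ± 0.18. The whole cytotoxic list differed by 0.59 ± 0.18, so it fell less. A smaller fall decides nothing between fewer gamma-delta or NK-type cells and a change within the CD4 T cells. The 4 receptor genes summed to 47.6 CPM in wild type and 13.8 CPM in the knockout. A change within the CD4 T cells was not tested.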
